A study of Caenorhabditis elegans with 2 samples.

How the data were processed

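The series measured where the TATA-binding protein TBP-1 sits on the genome of the nematode Caenorhabditis elegans, by chromatin immunoprecipitation followed by sequencing. TBP-1 is the worm's TATA-binding protein, a general transcription factor used by RNA polymerases I, II and III. Per the labels, whole animals of a transgenic strain that carries a GFP-tagged tbp-1 gene together with a rescuing copy of unc-119 were collected as young adults, 65 hours old, after synchronisation by starvation at the first larval stage. Chromatin was sheared by sonication and precipitated with an antibody against GFP. The labels give 1 group of 2 biological replicates, so the p-values below compare genes or positions within these libraries, not conditions.

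Each list gives peaks on the ce11 assembly in narrowPeak format, per the deposited file descriptions. The authors deposited 1 list per replicate, 1 list called on both replicates pooled, and 1 list of reproducible peaks thresholded by IDR, the irreproducible discovery rate, which keeps peaks whose rank repeats between replicates. The replicate and pooled lists hold 30000 peaks each and were described as input for that procedure, background included. All were called against a control alignment, which was not analysed here. The peak caller, the aligner and their versions are not given in the sources used here. The number of reads behind each library is unknown, so no interval that needs the depth is given.

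The deposited signal value of each peak is the authors' own, on a scale that no source used here states, and it served only to rank peaks within a list. The deposited −log10 q value of each peak was at its maximum of 3.96 for all 3862 reproducible peaks and could not rank them. The summit position within each peak was used as deposited. All 3862 reproducible peaks were found, with the same position and signal, among the 3862 strongest peaks of the pooled list. The reproducible list is therefore a rank threshold on the pooled list rather than a filter applied to each peak. No peak lay beyond a chromosome end of the reference used here, WBcel235, the same build as ce11, with gene models of Ensembl release 115. Widths are partly fixed: 2031 reproducible peaks are 330 bp wide, and the most frequent width was 336 bp in replicate 1 and 480 bp in replicate 2. In the reproducible list 32 intervals repeat another one.

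A gene counted as occupied when a reproducible summit lay within 500 bp of the 5' end of any of its annotated transcripts. The share of summits near 5' ends was tested against 10000 circular shifts of the summits along each chromosome, a one-sided permutation test. Gene classes with at least 10 genes were compared with protein-coding genes, and 24 gene lists with all other protein-coding genes, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment. Intervals on shares of genes are exact 95% binomial (Clopper-Pearson) intervals and describe counts of genes, which are not replicates. Genes that share a peak or an operon are not independent, which makes such p-values too small. Where a p-value fell under 1e-300 it was set to 1e-300. Signal ranks were compared by a two-sided permutation test of the difference of median percentiles with 100000 resamples. Summit positions are medians with a bootstrap interval from 2000 draws over genes. Motifs were counted on either strand within 100 bp of summits and in windows of the same size 1000 bp to each side. Replicates were compared by overlap of at least 1 bp with the 3862 strongest peaks of each replicate, and by Spearman correlation across peaks.

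The rule for genes to be named was fixed before the data were examined: tbp-1, unc-119 and ama-1; the protein-coding genes nearest to the 10 strongest peaks present in both replicates, and to the 10 strongest such peaks with only protein-coding 5' ends in reach; the gene with the strongest peak in each noncoding class; the 3 members with the strongest peaks in each gene list that passed, and up to 2 unoccupied members of lists that were mostly occupied; and members of 5 or fewer that differed from the rest of their list. Genes named outside this rule are said to be so where they appear. The gene lists, which select protein-coding genes by symbol and may overlap, the tests and most alternatives were fixed at the same time. The alternatives were the 1931 strongest peaks, windows of 250 and 1000 bp, each replicate's own 3862 strongest peaks, gene-model 5' ends, each summit assigned to its nearest 5' end, the peak interval in place of the summit, an overlap of 50% of both peaks, a doubled number of replicate peaks, a comparison set of genes with a symbol, a 50 bp motif window, control windows 500 bp away, and the omission of 20 kb around tbp-1 and unc-119. A split of the motif counts by neighbouring gene class, and the gene lists without genes near tRNA, snoRNA or snRNA genes, were chosen after seeing the data.

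The computations ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. They were tested on simulated data. With randomly placed peaks, 0 of 20 draws gave a shift test under 0.05, and 1 of 480 list tests passed over 19973 protein-coding genes. With summits placed on the gene 5' ends of 60% of the members of 6 lists, 120 of 120 list tests recovered these lists. Of the lists that had not been seeded, 22 of 360 tests passed. Recovery at lower occupancy, which most lists called above other genes had, was not simulated. With 40% of the peaks placed at 5' ends, the share near starts was recovered to within 1.54 percentage points in each of 20 draws over 46890 genes. With ranks shuffled, the signal difference was -2.23 percentage points. With 7.77% of summits placed on B box matches and the rest at random, 8.08% of summits had a match, and the difference from control windows was 6.84 points, lower than the share placed.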

Results

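Binding of the GFP-tagged TATA-binding protein TBP-1 was profiled in whole young adult Caenorhabditis elegans, in 1 group of 2 biological replicates with no second condition. The comparisons below are therefore between gene classes, gene groups and regions within the same animals. The reproducible list held 3862 peaks covering 1227 kb, or 1.22% of the 6 chromosomes. Peaks were most dense on chromosome III, at 49.5 per Mb, and least dense on chromosome V, at 30.1 per Mb. Chromosomes IV, I, II and X held 41.5, 39.9, 38.3 and 36.1 peaks per Mb. Depth is unknown, since the files give peaks and no read totals.

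The replicates ranked the same sites highest. Of the 3862 reproducible peaks, 2958 (76.6%) overlapped one of the 3862 strongest peaks of both replicates, 798 did so in 1 replicate and 106 in neither. Circularly shifted peaks gave 1.92% on average (one-sided permutation test with 10000 shifts, p = 1e-04, the smallest they can give). All 386 peaks of the strongest 10th were shared by both replicates, against 50 of the 386 weakest. Across the 3829 peaks matched in both replicates, the signal had a Spearman correlation of 0.861. This correlation is across peaks, which are not independent replicates, and the peaks were selected on the pooled signal of both replicates, so neither value is independent evidence of concordance.

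The strongest TBP-1 peaks lay at genes for small structural RNAs, and peaks at protein-coding genes were weaker. Among the 386 strongest peaks, 306 (79.3%) had a tRNA 5' end within 500 bp, 46 had an snoRNA, snRNA or rRNA 5' end without a tRNA, and 9 had protein-coding ends without any of these. In the later 10ths, from number 3 to number 10, protein-coding ends led, at 41.7% to 51.8% of peaks. Over all 3862 peaks, 522 had a tRNA end, 227 an snoRNA, snRNA or rRNA end, 1560 a protein-coding end, and 331 another noncoding or pseudogene end, each counted in the first of these that applied, while 1222 had none. In total 2640 summits (68.4%) lay near an annotated 5' end, against 33.9% for shifted summits (95% of shifts from 32.4% to 35.4%; one-sided permutation test, p = 1e-04, the smallest that 10000 shifts can give).

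**Figure D1:**
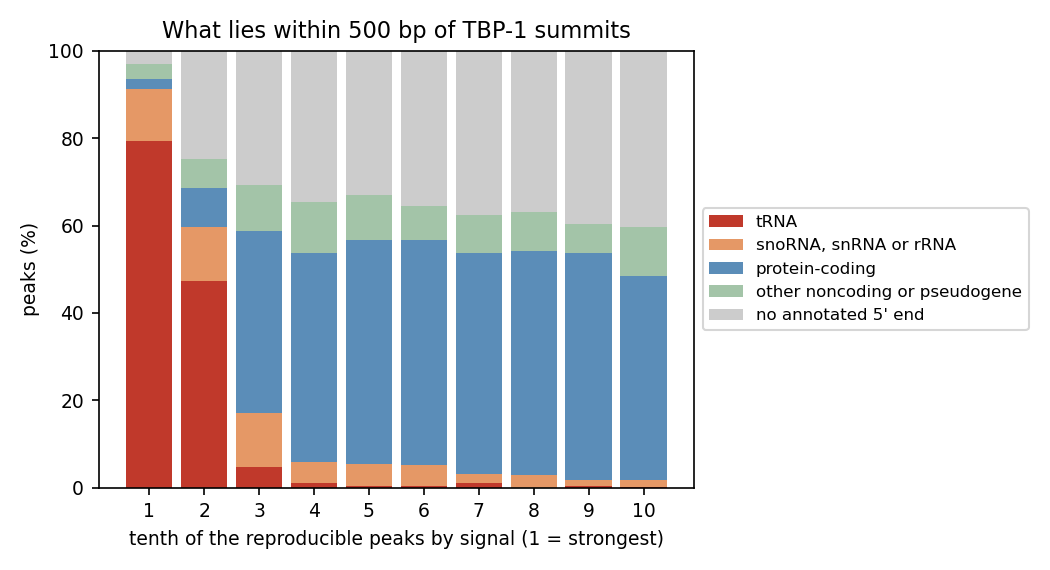
Share of reproducible TBP-1 peaks (y axis, %) by what lies within 500 bp of the summit, in 10 equal parts of the list ordered by signal (x axis, 1 is the strongest). Each peak counts once, in the first class of the legend that applies; tRNA genes take 79.3% of the strongest peaks and 47.4% of the next, and protein-coding genes lead from part 3 on.

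Of the 10 strongest peaks, 8 had an snoRNA gene and 2 a tRNA gene as the nearest small RNA gene. The strongest of all, on chromosome V from 15873666 to 15874290 (ce11), had its summit at -55 bp from the 5' end of T06C12.16, an snoRNA gene; snoRNAs guide the chemical modification of other RNAs. It ranked 1 in both replicates. The next ones lay at the snoRNA genes F55A11.10 (chromosome V, 11782614 to 11783276), ZK265.10 (chromosome I, 8259287 to 8259895) and B0334.12 (chromosome II, 11484545 to 11485122), and ranked 2 to 4; these 3 genes are named after their values were seen. Protein-coding 5' ends within reach of the 10 strongest peaks were those of F55A11.6, of twk-5, a potassium channel gene, and of wrt-3, a hedgehog-related gene, each beside an snoRNA gene. The strongest peak at a tRNA gene was on chromosome X from 3035768 to 3036438, ranked 6 in the list and in both replicates.

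Almost every tRNA gene was occupied. A summit lay within 500 bp of the 5' end of 579 of 612 tRNA genes (94.6%, 95% interval 92.5% to 96.3%), against 2035 of 19973 protein-coding genes (10.2%, 9.77% to 10.6%). Peaks of either replicate alone occupied 580 and 574 tRNA genes. The snRNA genes followed with 76 of 129 (58.9%), then snoRNA genes with 141 of 346 (40.8%), microRNA genes with 43 of 261 (16.5%) and other ncRNA genes with 915 of 7764 (11.8%). These 5 classes lay above protein-coding genes (two-sided Fisher's exact tests, adjusted p = 1e-300 for tRNA, the smallest value kept, 6.87e-41 for snRNA, 4.88e-48 for snoRNA, 0.00273 for microRNA and 0.000205 for other ncRNA). Shares lower than that of protein-coding genes were found for pseudogenes, 110 of 2128 (5.17%), and for piRNA genes, 282 of 15363 (1.84%), with exact test adjusted p = 2.87e-15 and 7.45e-249. Against circularly shifted peaks these 2 classes parted. The mean of 200 shifts was 3.55% for pseudogenes, below their share, and 3.96% for piRNA genes, above theirs. For protein-coding genes that mean was 4.42%. No p-value was computed for these differences from shifted peaks. The pseudogene share was 3.24% with the 1931 strongest peaks, and the piRNA share ranged from 0.443% with nearest ends to 4.11% with a 1000 bp window. Occupancy of lincRNA genes (19 of 194), antisense RNA genes (5 of 100) and rRNA genes (3 of 20) did not differ detectably from that of protein-coding genes (exact test adjusted p = 1, 0.12 and 0.5); with replicate 2 alone 1 rRNA gene was occupied. With each summit assigned to its nearest 5' end alone, the other ncRNA genes fell to 3.93%, below protein-coding genes, and with a 1000 bp window (14.2%) their call was lost (exact test adjusted p from 1.97e-39 to 0.2 over 8 alternatives). The microRNA call was lost with nearest ends (6.90%) and with a 250 bp window (8.81%; exact test adjusted p from 9.97e-06 to 1 over 8 alternatives).

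**Figure D2:**
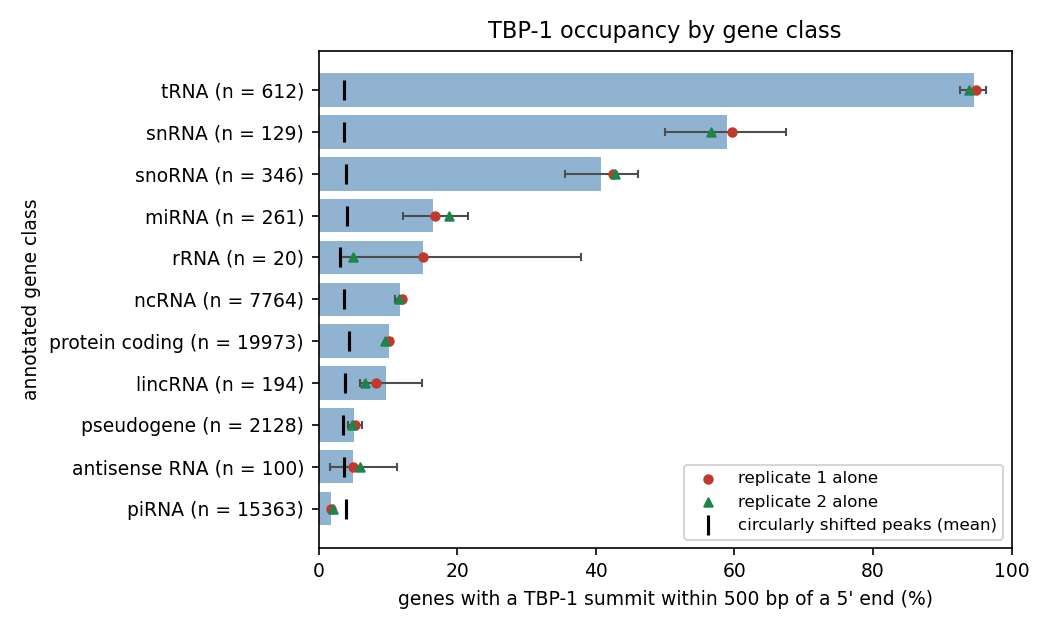
Share of genes of each annotated class (y axis, with the number of genes) that had a TBP-1 summit within 500 bp of a 5' end (x axis, %). Bars give the reproducible peaks with exact 95% binomial intervals, points each replicate's own strongest 3862 peaks, and ticks the mean of circularly shifted peaks; tRNA genes reach 94.6% against 3.67% for shifted peaks, and piRNA genes stay at 1.84%.

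The strongest peak of each noncoding class was as a rule one it shared with a tRNA or snoRNA gene. This held for the antisense RNA anr-5, the lincRNA linc-44, the piRNA 21ur-5229 and the snRNA gene sls-2.9, whose peaks had a tRNA 5' end in reach, and for the ncRNA F55A11.13, which shared the peak of F55A11.10. It also held for the strongest pseudogene peak (chromosome IV, rank 86), which had an snoRNA end in reach. The microRNA gene cel-mir-51 was an exception: its peak on chromosome IV, with a summit at -99 bp from the annotated end, ranked 58 with no tRNA or snoRNA end in reach. The strongest peak at an rRNA gene, rrn-4.15 (5S rRNA, chromosome V), ranked 571 and was another exception, with no tRNA or snoRNA end in reach.

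Signal ranks separated the classes in both replicates. Peaks with a tRNA end had a median signal percentile of 91.4 (interquartile range 87.2 to 95.3, 522 peaks) and peaks with protein-coding ends alone a median of 39.6 (19.7 to 59.3, 1342 peaks), a difference of 51.8 percentage points (two-sided permutation test, p = 1e-05, the smallest that 100000 resamples can give). The difference was 52.7 points in replicate 1 and 51.7 points in replicate 2.

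Among peaks with protein-coding ends alone, the strongest lay at sms-3, a sphingomyelin synthase gene, which was the nearest gene of 3 of the 10. The first of them (chromosome III, 1600628 to 1601151, rank 105) had its summit in an intron of sms-3. The remaining genes were zip-7 (rank 137), W08A12.2 (rank 174), Y65B4A.2 (rank 473), the ribosomal protein gene rpl-3 (rank 535), Y43F8B.17 (rank 582), tos-1 (rank 592) and tasp-1 (rank 596). A match to the B box, the internal promoter element of tRNA genes, lay within 100 bp of 2 of these 10 summits, both nearest to sms-3.

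The summit sat close to the annotated 5' end of tRNA genes and farther upstream at protein-coding genes. The median position was -16 bp at 579 tRNA genes (interquartile range -21 to 3 bp, 95% bootstrap interval -17 to -15 bp) and -176 bp at 2035 protein-coding genes (-287 to -61 bp, bootstrap interval -185 to -167 bp), negative values being upstream. Summits lay upstream of the end at 85.4% of these protein-coding genes. The medians were -57 bp at 141 snoRNA genes and -20 bp at 76 snRNA genes. The window bounds these distances, and with 250 bp the protein-coding median was -127 bp. Many worm messenger RNAs are trans-spliced, with another RNA attached to their 5' end, so annotated ends can lie downstream of the initiation site. The protein-coding distances are therefore from annotated ends and not from measured initiation sites.

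**Figure D3:**
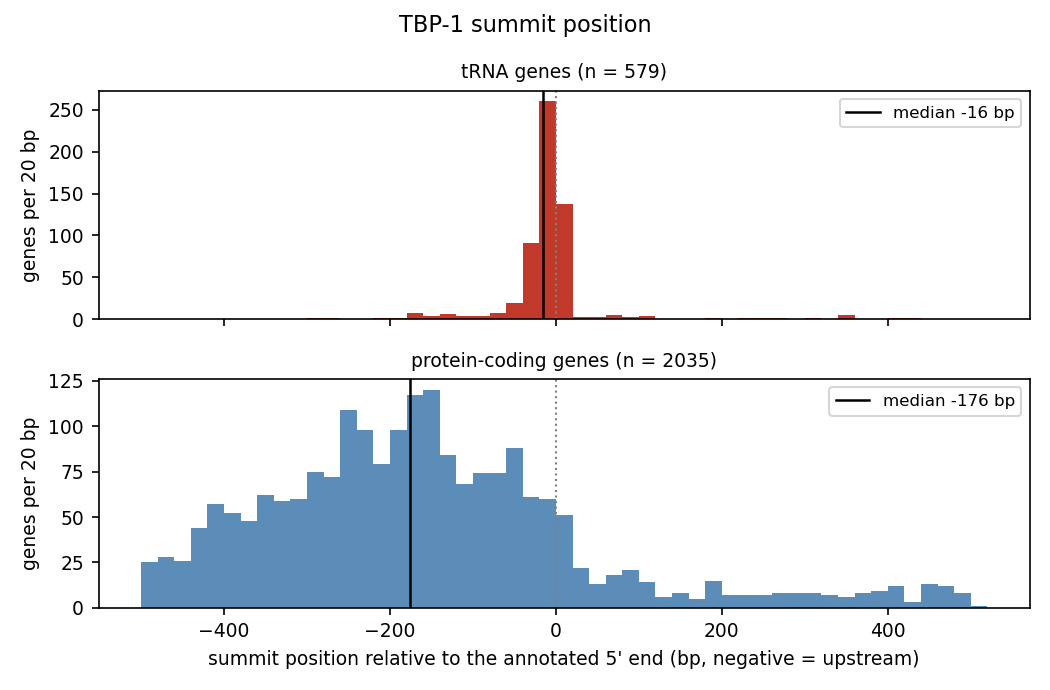
Number of genes per 20 bp bin (y axis) by the position of the nearest TBP-1 summit relative to the annotated 5' end (x axis, bp, negative is upstream), for 579 tRNA genes above and 2035 protein-coding genes below. Solid lines mark the medians, -16 bp and -176 bp, and dotted lines the annotated end; tRNA positions are narrow and protein-coding positions broad.

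Ribosomal protein and translation factor genes were occupied more often than other protein-coding genes. The background itself depends on the setting. Of all 19973 protein-coding genes, 2035 had a peak in the main setting, 1274 with a 250 bp window and 911 with the 1931 strongest peaks. List shares under these alternatives, here and below, are to be read against those lower counts. Of the cytosolic ribosomal protein genes, 66 of 81 (81.5%, 95% interval 71.3% to 89.2%) had a peak, against 9.90% of other protein-coding genes (two-sided Fisher's exact test, adjusted p = 5.53e-50). Their strongest peaks were at rpl-3, rpl-20 (rank 604) and rpl-15 (rank 607), with summits at -276, -292 and -354 bp from the annotated end, while rpl-41.1 and rpl-25.2 were among the 15 without a peak. The share fell to 23.5% with a 250 bp window and 40.7% with nearest ends, past the threshold in each, so the place of this list among the others depends on the window and the assignment. Translation factors were occupied in 17 of 39 genes (exact test adjusted p = 3.51e-07), led by iff-2, eif-3.C and eef-1A.1, the last a translation elongation factor; the share was 43.6%, and 28.2% with a 250 bp window and 20.5% with the 1931 strongest peaks. Mitochondrial ribosomal protein genes were occupied in 17 of 70 (24.3%, exact test adjusted p = 0.00126), led by mrps-7, mrpl-28 and mrpl-49. With the 1931 strongest peaks this last call was lost at 7.14% occupied (exact test adjusted p from 9.64e-05 to 0.404 over 10 alternatives).

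Other housekeeping groups were above the rest as well. Respiratory chain genes had a peak in 24 of 59 (40.7%, exact test adjusted p = 6.87e-09), led by the cytochrome oxidase subunit genes cox-5B, cox-5A and cox-6B. Their share was 23.7% with a 250 bp window, and 22% with nearest ends and with the 1931 strongest peaks, past the threshold in each. Proteasome subunit genes had one in 15 of 33 (45.5%, exact test adjusted p = 7.52e-07), led by rpn-3, rpn-9 and rpn-11. With the 1931 strongest peaks, 9.09% of them had one, while 911 of 19973 protein-coding genes did. The call was then lost (exact test adjusted p from 1.9e-07 to 0.325 over 10 alternatives). Constitutive chaperone genes had one in 10 of 15 (66.7%, exact test adjusted p = 7.52e-07), among them hsp-1, cct-8 and hsp-110, and not in cct-3 or hsp-4. The hsp-110 peak was also the rpn-3 peak. The chaperone call depended on the assignment: with a 250 bp window 20% were occupied, and with each summit given to its nearest 5' end 6.67%, neither past the threshold (exact test adjusted p from 2.57e-08 to 1 over 10 alternatives). Spliceosome genes had a peak in 7 of 20 (exact test adjusted p = 0.00529), led by snr-4, snr-1 and prp-8, and this call was lost under the same settings, at 15% in each (exact test adjusted p from 0.000248 to 0.208 over 10 alternatives). The snr-4 peak also had an snRNA end in reach. Genes for RNA polymerase II and its general factors had one in 11 of 42 (26.2%, exact test adjusted p = 0.00529), led by taf-4, rpb-11 and rpb-12. Replicate 2 alone, at 19%, and the 1931 strongest peaks, at 9.52%, did not give that call (exact test adjusted p from 0.00243 to 0.228 over 10 alternatives). tbp-1 itself had a peak of rank 1585, and ama-1, the gene of the largest RNA polymerase II subunit, had none. Histone genes had a peak in 16 of 80 (20%, exact test adjusted p = 0.0149), led by his-67 and his-68, which share a peak, and his-37. This call was lost with replicate 1 alone, at 17.5%, and against genes with a symbol (exact test adjusted p from 0.00131 to 0.0773 over 10 alternatives).

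Germline genes were occupied more often than other protein-coding genes. Of 35 germline and oocyte genes, 17 (48.6%) had a peak (exact test adjusted p = 5.81e-08), led by puf-3 and puf-11, which encode RNA-binding proteins, and rme-2, the yolk receptor of oocytes. Their share was 31.4% with a 250 bp window and 20% with the 1931 strongest peaks, past the threshold in both. Vitellogenin genes, which encode yolk proteins made in the intestine, had a peak in 3 of 6 (vit-6, vit-1 and vit-2; exact test adjusted p = 0.0267), all ranked 2912 or weaker. The vitellogenin call was lost with replicate 1 alone, where 2 had a peak, with a 1000 bp window, and with the 1931 strongest peaks, where 0% had one (exact test adjusted p from 0.00826 to 1 over 10 alternatives). The heat shock genes had a peak in 4 of 9 (exact test adjusted p = 0.0152), led by F44E5.4 and F44E5.5, which share a peak, and hsp-16.2. With nearest ends, and with the 1931 strongest peaks, 22.2% were occupied and the call was lost (exact test adjusted p from 0.000715 to 0.183 over 10 alternatives). Lists of 5 other kinds of gene did not pass: intestine 5 of 25 (act-5, pept-1 and the vitellogenin genes named above), muscle 2 of 26 (act-2 and act-4), neurons 1 of 21 (unc-31), RNA polymerase III and its factors 1 of 15 (snpc-3.4) and aminoacyl-tRNA synthetases 7 of 32 (exact test adjusted p = 0.119, 1, 0.782, 1 and 0.052). The intestine list passed with a 250 bp window and with nearest ends (exact test adjusted p from 0.0286 to 0.803 over 10 alternatives); its share of 20% fell to 12% with replicate 1 alone and to 0% with the 1931 strongest peaks. The vit-1 and pept-1 peaks ranked 4249 and 3933 in replicate 1 and were not among the strongest peaks of both replicates compared above. The unc-31 peak also had an snRNA end in reach, and without genes near tRNA, snoRNA or snRNA genes 0 of 20 neuron genes had a peak. With replicate 2 alone, 9.52% of the neuron list and 4.76% of the ceh genes had a peak. The synthetase list passed with nearest ends, with replicate 2 alone and without genes near tRNA, snoRNA or snRNA genes (exact test adjusted p from 0.0112 to 1 over 10 alternatives); its share of 21.9% was 12.5% with a 250 bp window and 3.13% with the 1931 strongest peaks.

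Chemoreceptor, C-type lectin and F-box A genes were occupied less often than other protein-coding genes. Of 1292 chemoreceptor genes 13 (1.01%) had a peak (exact test adjusted p = 4e-43), of 240 C-type lectin genes 7 (2.92%, exact test adjusted p = 0.000103) and of 170 F-box A genes 4 (2.35%, exact test adjusted p = 0.000453). These calls held in all 10 alternatives, with shares from 0.619% to 2.01%, 0.833% to 4.58% and 0.588% to 4.12%. Several of their strongest peaks were shared with a tRNA gene: those of srh-269, srd-44 and srz-58 among chemoreceptors and that of clec-126 among lectins. The other lectin genes with the strongest peaks were clec-57 and clec-80, and the F-box A genes were fbxa-106, fbxa-108 and fbxa-76. The clec-57 peak also had an snRNA end in reach. The peaks of clec-80, fbxa-108 and fbxa-76 were not among the strongest peaks of both replicates compared above. The clec-80 and fbxa-76 peaks ranked 7664 and 13588 in replicate 2, and the fbxa-108 peak ranked 4280 in replicate 1. No occupied member of the ribosomal protein, proteasome, respiratory chain or germline lists had a tRNA end at its peak. However, 17 of the 81 cytosolic ribosomal protein genes lay near a tRNA, snoRNA or snRNA gene. Without them, 50 of 64 had a peak (exact test adjusted p = 2.37e-38). The occupied counts of the mitochondrial ribosomal protein, proteasome, respiratory chain and germline lists stayed at 17, 15, 24 and 17 without such genes. Nuclear hormone receptor genes had a peak in 16 of 269 (5.95%, exact test adjusted p = 0.0287), led by nhr-41, nhr-47 and nhr-68. Collagen genes had one in 8 of 156 (5.13%, exact test adjusted p = 0.0467), led by col-54, col-85 and col-40. The peaks of nhr-41, col-54 and col-85 also had a tRNA end, as did that of the homeobox gene ceh-43, named below. The collagen call was lost with either replicate alone, each at 5.77%, with gene-model ends and with the 1931 strongest peaks (exact test adjusted p from 0.00183 to 0.71 over 10 alternatives). The collagen share was 0.641% with a 250 bp window, 1.28% with nearest ends and 3.21% with the 1931 strongest peaks. The receptor call was lost with nearest ends, peak intervals, the 1931 strongest peaks, and without genes near tRNA, snoRNA or snRNA genes (exact test adjusted p from 0.000916 to 0.283 over 10 alternatives), with shares from 1.86% to 8.92%. The homeobox ceh genes, with 2 of 63 occupied (ceh-43 and ceh-38), and the major sperm protein genes, with 0 of 31, did not pass (exact test adjusted p = 0.108 and 0.0871). Both passed against genes with a symbol (exact test adjusted p from 0.0309 to 1 for ceh genes and from 0.0383 to 0.567 for sperm protein genes over 10 alternatives).

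**Figure D4:**
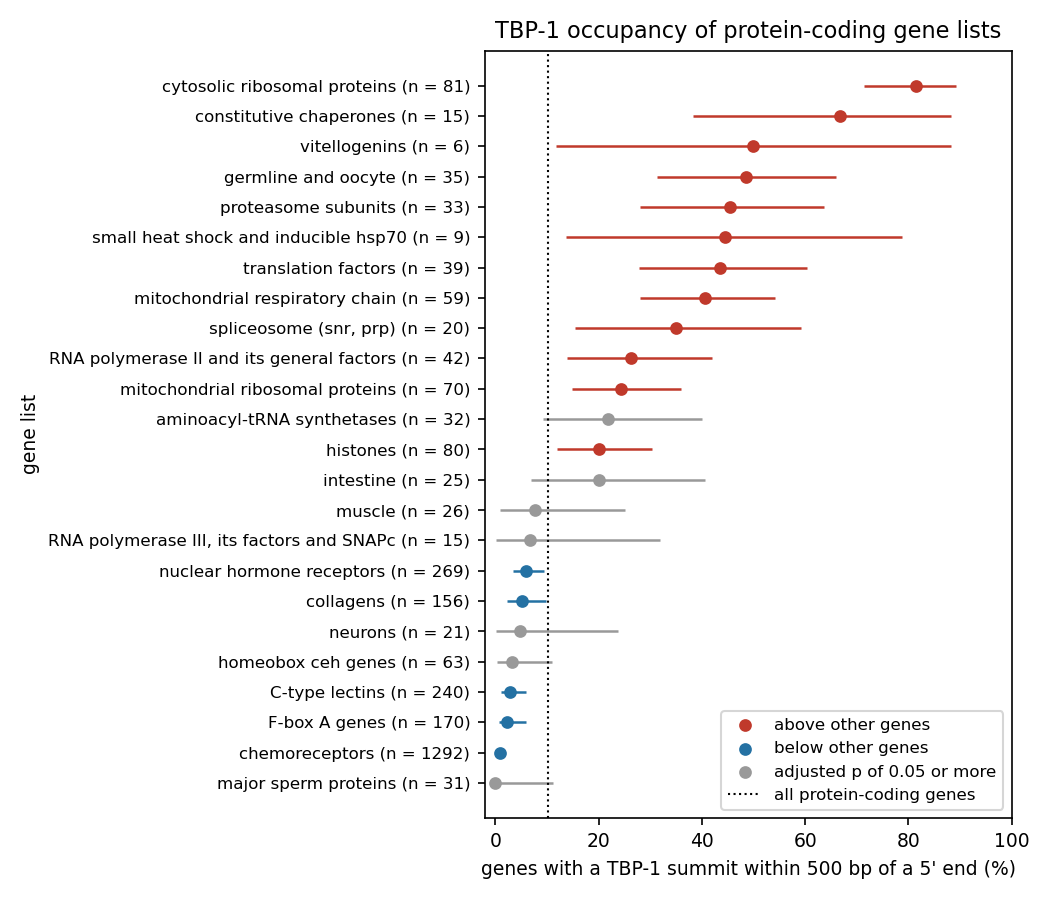
Share of genes in each of the 24 lists (y axis, with the number of genes) that had a TBP-1 summit within 500 bp of a 5' end (x axis, %), with exact 95% binomial intervals over genes as lines. Red lists lie above and blue lists below other protein-coding genes at an adjusted p under 0.05; the dotted line is the share of all protein-coding genes, 10.2%, and cytosolic ribosomal proteins reach 81.5%.

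Protein-coding genes of the X chromosome were less often occupied than those of autosomes. A peak lay at 175 of 2731 genes on X (6.41%) and at 1860 of 17242 autosomal genes (10.8%), a difference of -4.38 percentage points (two-sided Fisher's exact test, p = 1.55e-13). It was -2.36 points with the 1931 strongest peaks, where 911 protein-coding genes had a peak in place of 2035. The smaller difference in points goes with this lower overall share, so it does not show a smaller relative deficit on X. Of the tRNA genes, 265 of 276 were occupied on X and 314 of 336 on autosomes, both close to all, so their occupancy says little on this point. The median signal percentile of peaks with a tRNA end was 90.8 on X and 91.9 on autosomes, a difference that was not tested. On autosomes, the middle part of each chromosome, of 3 equal parts, held 766 occupied genes of 6570 (11.7%) and the outer parts 1094 of 10672 (10.3%; exact test, p = 0.00396). That call was lost with a 250 bp window and with the 1931 strongest peaks (exact test p from 0.00087 to 0.716 over 7 alternatives).

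Sequence at the summits was richer in the B box, mostly at tRNA genes, and in GA repeats than the flanks, and not in the TATA box. A B box match lay within 100 bp of 578 of 3862 summits (15%), against 1.5% of control windows (two-sided Fisher's exact test, adjusted p = 1.37e-172). This difference of 13.5 percentage points was 1.49 points within 50 bp of summits and 23.1 points at the 1931 strongest peaks, past the threshold in both. The GA repeat, a run of 8 bases, was found at 6.71% of summits and 1.68% of controls (exact test adjusted p = 6.72e-42), a difference of 5.02 points that was 3.29 points within 50 bp and 2.95 points at the 1931 strongest peaks. The TATA box was found at 15.8% of summits and 18.9% of controls (exact test adjusted p = 4.33e-05), and a run of 8 T at 14% and 21.3% (exact test adjusted p = 6.21e-22). The median GC content was 42.3% at summits and 36.8% in controls, a difference of 5.47 points that was 9.9 points within 50 bp, which bears on both of these AT-rich motifs. Split by neighbouring genes, a split chosen after seeing the data, summits with protein-coding ends alone had the TATA box in 16.9% against 16.6% of controls (exact test adjusted p = 0.788), GA repeats in 5.89% against 1.27% (exact test adjusted p = 3.12e-15) and the B box in 2.16% against 0.559% (exact test adjusted p = 1.99e-05). GA repeats were above controls elsewhere too. Their shares were 9.17% against 2.41% without an annotated 5' end, and 3.07% against 0.958% with a tRNA end. The TATA box was below controls in those groups, at 14.9% against 19.9% and 13% against 23.1%. With protein-coding ends alone, a run of 8 T lay at 15.9% of summits and 18.7% of controls (exact test adjusted p = 0.0316). Of the 578 summits with a B box, 324 had a tRNA end. These 324 are 62.1% of the 522 summits with a tRNA end, against 1.92% of the controls of those summits (exact test adjusted p = 3.66e-165).

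The 1222 summits away from annotated 5' ends lay mostly between genes. Of these, 707 (57.9%) were between genes, 370 (30.3%) in introns and 145 (11.9%) in exons, while the genome that far from 5' ends is 32% between genes, 36.6% intron and 31.4% exon. Their median signal percentile was 41.1, close to the 40.4 of peaks assigned to protein-coding ends. The strongest, on chromosome X from 1837663 to 1838150 (rank 74), lay in an intron of a pseudogene, and the next, on chromosome V from 53185 to 53722 (rank 78), in an intron of the chemoreceptor gene srt-52, also named after its values were seen.

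The loci carried by the transgene were examined because extra copies can raise signal and background. Within 20 kb of tbp-1 (chromosome III, 7384033 to 7386124) lay 10 reproducible peaks, and a median of 1 lay around protein-coding genes; 40 of 19973 genes (0.2%) had as many. In the pooled list of 30000 peaks the locus held 24 against a median of 11, and 2751 genes (13.8%) had as many. The strongest of the 10, from 7387315 to 7387872, ranked 18 in the list and in both replicates and had its summit at -11 bp from the 5' end of the annotated ncRNA gene T20B12.12, named here after its values were seen. The other 9 ranked from 898 to 3638. Within 20 kb of unc-119 (chromosome III, 10902641 to 10908935) there was no reproducible peak and 1 pooled peak. Whether the tagged copy of tbp-1 accounts for any of the 10 peaks cannot be read from these lists.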

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

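No test in this part was chosen after its own result was seen; the density that prompted them had been. Peaks below the reproducible threshold, which the comparisons above do not use, were concentrated over the piRNA clusters of chromosome IV. In the 110 of 350 bins of 50 kb with at least 20 piRNA 5' ends, the pooled list held 545 such peaks per Mb against 274 per Mb elsewhere on the chromosome, a ratio of 1.99. The ratio was 1.84 in replicate 1 and 1.73 in replicate 2, and 0.961 for the peaks above the threshold. A median of 100% of the 31-mers in these peaks were unique in the genome, the outcome predicted without repeated sequence. If reads with several placements were dropped before peak calling, that outcome was fixed, so it decides little. Binding at single piRNA genes stays open: 44.1% of the summits lay within 100 bp of a piRNA 5' end, 1.16 times the 38.1% of summits moved by 2 to 10 kb (permutation test with 1000 moves, p = 0.001, the smallest they can give), which is short of the 1.2 times set beforehand. A broad property of these domains could also raise the background there, and the control alignment that might separate the possibilities was not analysed here. The design has 1 group, so no condition could be set against these explanations.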

How the results depend on the processing

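All alternatives here were fixed before the data were examined, except the lists without genes near tRNA, snoRNA or snRNA genes. Of 427 values recomputed under alternatives, 382 kept their direction and side of the threshold or stayed within their spread or 1.5 times the count. With each summit given to its nearest 5' end, ncRNA genes reversed to 3.93% occupied, and the constitutive chaperone call was lost at 6.67%. The classes above protein-coding genes then fell from 5 to 3. A gene sharing a summit with a nearer end loses it under this setting. With the 1931 strongest peaks, the covered length was 619 kb, the Spearman correlation 0.949, the protein-coding summit position -189 bp, and the lists above and below other genes 7 and 3 in place of 12 and 5, with 0% of vitellogenin genes occupied. Fewer peaks cover less sequence, and the peaks of the occupied vitellogenin genes all ranked 2912 or weaker, outside the 1931 strongest. For the other changes the cause was not tested. The middle parts of autosomes then exceeded the outer parts by 0.127 percentage points, and with a 250 bp window by 0.498 points, short of the exact test's threshold; the cause was not tested. The 250 bp window, which bounds distances, gave a protein-coding position of -127 bp. An overlap of 50% of both peaks gave a correlation of 0.846, over 3374 matched peaks. Without 1 replicate, the covered length was 1265 to 1620 kb, the higher value from the wider peaks of replicate 2. Depth limits could not be examined, since no read totals are given.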

Other observations

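The tests below had their predictions written before their results were seen, while the splits of snRNA and snoRNA genes were chosen after seeing the data. The snRNA class held an unequal pair of trans-splicing RNA families, whose products are attached to the 5' ends of many worm messenger RNAs. All 18 SL2 RNA genes had a reproducible peak, in both replicates, against 1 of 12 SL1 RNA genes (two-sided Fisher's exact test, p = 2.2e-07). Of the other 99 snRNA genes, 57 had one. The 5S rRNA genes had a peak in 3 of 16, and the 4 other rRNA genes had none. Replicate 1 alone gave 1 SL1 and 3 5S rRNA genes, and replicate 2 alone gave 0 and 1. Among snoRNA genes, 62 of 130 outside protein-coding genes were occupied and 20 of 33 inside a gene of the opposite strand, against 59 of 183 inside a gene of the same strand (32.2%), from whose transcript they can be processed (exact tests, p = 0.00675 and 0.00288).

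A B box was weighed as a hypothesis for peaks at snoRNA genes, weak ones included. A match from 150 bp upstream to the 3' end was found in 10 of 141 occupied snoRNA genes and 0 of 205 others, a difference of 7.09 percentage points (exact test, p = 0.000104), under the 20 points set beforehand. The element may serve a few of these genes, and most occupied snoRNA genes had no match, so what marks them stays open. The same pattern matched only 64.1% of occupied tRNA genes, so a gene without a match may still hold a B box.

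Genes without peaks were examined next. Within 250 bp of the 5' ends of the SL1 and rRNA genes together, a median of 0% of the 31-mers were unique in the genome. The median was 0% at the 12 SL1 genes, 7.34% at the 16 5S rRNA genes, 40.9% (interquartile range 0% to 86.3%) at the 4 other rRNA genes and 87.9% at SL2 RNA genes, so reads that cannot be placed uniquely are a candidate explanation for the contrast between SL1 and SL2. The 4 other rRNA genes are too few to be read alone. The sperm protein genes, with no peak at 31 genes, had a median of 46.6% (interquartile range 33.6% to 60.5%) against 100% at other protein-coding genes, also in line with lost reads, while silence of these genes in young adults was not tested. The 33 tRNA genes without a peak were different. Their median was 88.3% unique (interquartile range 55.5% to 97.7%), between the bounds set beforehand, against 87.9% (84.7% to 89.4%) at occupied tRNA genes. The wider spread includes less unique genes, so unplaced reads stay open for a part of them. Loss of the B box, as counted by this sequence pattern, was argued against. The share with a match was 64.1% in occupied and 69.7% in unoccupied genes, a difference of -5.62 points (exact test, p = 0.579).

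Peaks away from annotated 5' ends came last. A median of 100% of the 31-mers in the 1222 peaks were unique, the outcome predicted without sequence present in several copies. The median over all reproducible peaks was also 100%. How reads with several placements were treated is not given. If they were dropped, peaks could hardly be called in repeated sequence, so this test decides little. Unannotated RNA polymerase III genes are a candidate for a part: 12.1% of these summits had a B box match against 1.96% of controls (exact test, p = 2.09e-35), and 27 of the 108 among the strongest 5th of all peaks. These counts are within 100 bp, and a 50 bp window was not tried for this group. Initiation upstream of trans-spliced or short 5' ends is a candidate for another part: 41.7% lay 500 to 2000 bp upstream of a protein-coding 5' end, 1.37 times the 30.4% of shifted summits (permutation test, p = 1e-04, the smallest that 10000 shifts can give). Shifted summits could also fall in exons and introns, while the observed ones lay mostly between genes. The excess is therefore not specific to upstream initiation. Enhancers and other bound elements were not tested, and the design has no second group to set against these explanations.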
